A study of Mus musculus with 3 samples.

How the data were processed

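High-throughput genome-wide translocation sequencing (HTGTS) was applied to genomic DNA of mouse splenic B cells that lacked CD43 and carried preassembled immunoglobulin loci. The cells had been cultured for 4 days with anti-CD40 at 1 ng/mL and IL-4 at 20 ng/mL, which induce class switching to IgG1 and IgE. In this method a primer in the 5′ part of the switch region Sμ (the bait) is extended across a junction into whatever sequence the broken end was joined to (the prey). Per the labels' protocols, AflII digestion removed unrearranged sequence and the libraries were read on a MiSeq. Per the submitters' processing notes, Bowtie2 and mm9 were used. Versions, filters and the caller of junctions are not given in the sources used here.

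The deposited workbooks hold, per library, a sheet of junction counts by region, prey strand and junction class, lists of single junctions by region, and lists of prey positions for 3 S regions. The counts are whole numbers of junctions as the authors deposited them, with no normalization. The other values, coordinates and alignment bounds of the single junctions, are positions in mm9 as the authors deposited them. The libraries were DNA-PKcs-/- replicate 5 with 842 junctions, DNA-PKcs PQR/PQR replicate 1 with 1681 junctions and PQR/PQR replicate 2 with 472 junctions. The authors also deposited a pool per genotype, with 12662 junctions for DNA-PKcs-/- and 4167 junctions for PQR/PQR. The pools contain these libraries, so pool values are given as the authors' pooled values and serve no main test. Some lines of the lists, and the list of Sμ junctions of PQR/PQR replicate 1, were not used here. That library's Sμ classes and positions come from its count and position sheets, its mean microhomology in Sμ is not analysed here, and its bait positions come from Sγ1 and Sε junctions. Wild-type cells are not analysed here.

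A junction was read as microhomology (MH) where bait and prey alignments overlap in the read, as direct where they abut, and as an insertion where unaligned bases lie between them. The classes computed this way from the lists were checked against the count sheets and were equal in every region without missing lines. A prey on the bait's strand is called deletional and one on the opposite strand inverted. Shares are given with Wilson 95% confidence intervals, and a count of 0 allows a share of up to 3 counts of the total, which is 0.356% of all junctions in DNA-PKcs-/- replicate 5. Reads carried no molecular identifiers, so intervals cover counting error only.

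Each share was compared between DNA-PKcs-/- replicate 5 and each PQR/PQR library by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 48 tests. Means over junctions were compared by two-sided permutation tests with 100000 resamples, adjusted over 19 tests. A difference was called when the adjusted p was below 0.05 in the same direction against every PQR/PQR library with the data. These tests on junctions compare libraries, not genotypes. A test between genotypes with 1 library against 2 has 3 possible splits and a smallest exact p of 0.333, and a given library is the highest or lowest of 3 by chance in 66.7% of cases. The labels do not say whether the PQR/PQR libraries come from separate mice, so their spread may be technical. The read names place DNA-PKcs-/- replicate 5 and PQR/PQR replicate 1 in the same sequencing run and PQR/PQR replicate 2 in another. The comparison with replicate 1 is therefore the one within a run.

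The results, tests, alternatives and the rule for naming items were fixed before the data were examined. The rule names all IgH regions, the 3 bins of 500 bp with most junctions per region and library, and the 3 chromosomes with most non-IgH junctions per library. Genes outside IgH, including a preset list of AID off-target genes, are not analysed here, because no annotation in mm9 coordinates was used. Constant genes are placed between S regions by their order in a GRCm38 table only. After the data had been seen, 5 results were added with 15 tests adjusted on their own. They are the share of other IgH junctions, its direct share, and the share of each S region's junctions outside the central 95% of the positions of all 3 libraries, from the 2.5th to the 97.5th percentile. The last replaced a share outside windows drawn around the PQR/PQR positions, which was dropped because those windows fixed the PQR/PQR value. The new limits still fix the share over all 3 libraries together, and most positions are PQR/PQR. Other settings were run that left out each PQR/PQR library, took the pools in place of the libraries, collapsed repeated junctions, added the sheet of large insertions, thinned the libraries to 472 junctions, required 50 bp of aligned prey, and changed the MH length, orientation, denominators and summaries of position. Medians were tested with 10000 resamples.

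The calling rule was tested on simulated data at the real numbers of junctions, with unadjusted p. With no difference in the direct share, 0.2% of 500 draws were called in Sγ1, 1.8% in Sε and 0.6% in Sμ. With a share lowered by 10 percentage points, 38.6%, 43.2% and 58.2% were called. With 20 points, 98.2%, 99.6% and 99.6% were called. The draws held counting error only, with no other spread between libraries, whereas the PQR/PQR libraries differed from each other in 3 planned results. False calls from such spread were therefore not measured. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.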

Results

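Junctions formed during class switch recombination were mapped in activated B cells that lacked DNA-PKcs, the kinase of classical non-homologous end joining, and in B cells homozygous for the PQR allele, which alters a phosphorylation cluster of that kinase. The comparison addresses whether junctions of PQR/PQR cells differ from those of DNA-PKcs-/- cells in the use of microhomology (MH, bases shared by both ends at the join), in their spread over the switch regions and in orientation. DNA-PKcs-/- replicate 5 gave 842 junctions, PQR/PQR replicate 1 gave 1681 junctions and PQR/PQR replicate 2 gave 472 junctions. Of 23 planned results, 12 were called, that is, DNA-PKcs-/- replicate 5 differed in the same direction from every PQR/PQR library with data. These are not all separate: the 3 region shares add up to the whole, and mean MH includes direct joins. The PQR/PQR libraries differed from each other in 3 of the 22 results that both could give. With 1 DNA-PKcs-/- library there is no replicate of that genotype, so all tests compare libraries.

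Of the S region junctions of DNA-PKcs-/- replicate 5, a smaller share lay in Sε, the switch region of IgE, and larger shares in Sγ1 and Sμ. The 3 shares add up to the whole, so a lower share of 1 region by itself raises the others. They are not separate results and give no rate of joining. Sε held 19.8% of its S region junctions (123 of 621, 95% CI 16.9 to 23.1), against 51.8% in PQR/PQR replicate 1 (794 of 1534, 49.3 to 54.3) and 42.0% in PQR/PQR replicate 2 (144 of 343, 36.9 to 47.3). Sγ1 held 34.0% (30.4 to 37.8) in DNA-PKcs-/-, against 17.7% (15.9 to 19.7) and 22.4% (18.4 to 27.2). Sμ, where joining gives internal deletions or inversions, held 46.2% (42.3 to 50.1), against 30.5% (28.3 to 32.9) and 35.6% (30.7 to 40.8). By Fisher's exact test the adjusted p against replicates 1 and 2 was 1.10e-42 and 6.25e-12 for Sε, 3.08e-14 and 6.44e-04 for Sγ1, and 9.53e-11 and 0.00392 for Sμ. The Sε share also differed between the PQR/PQR libraries, with an adjusted Fisher's exact p of 0.00371. With the authors' PQR/PQR pool in place of the libraries, the Sγ1 difference of 13.9 percentage points turned to -20.8 and the Sε difference of -27.1 points shrank to -5.00, while the Sμ difference grew to 25.8. With the authors' DNA-PKcs-/- pool the Sμ difference of 13.2 points turned to -2.39, and those of Sγ1 and Sε were 43.6 and -41.2. Few Sγ1 junctions of DNA-PKcs-/- replicate 5 and PQR/PQR replicates 1 and 2 lay from 114572107 to 114575342 (2.37%, 4.78% and 2.60%). This span held 35.7% of the Sγ1 junctions of the DNA-PKcs-/- pool outside replicate 5. The cause is not known here, so the Sγ1 shares carry this limit.

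**Figure D1:**
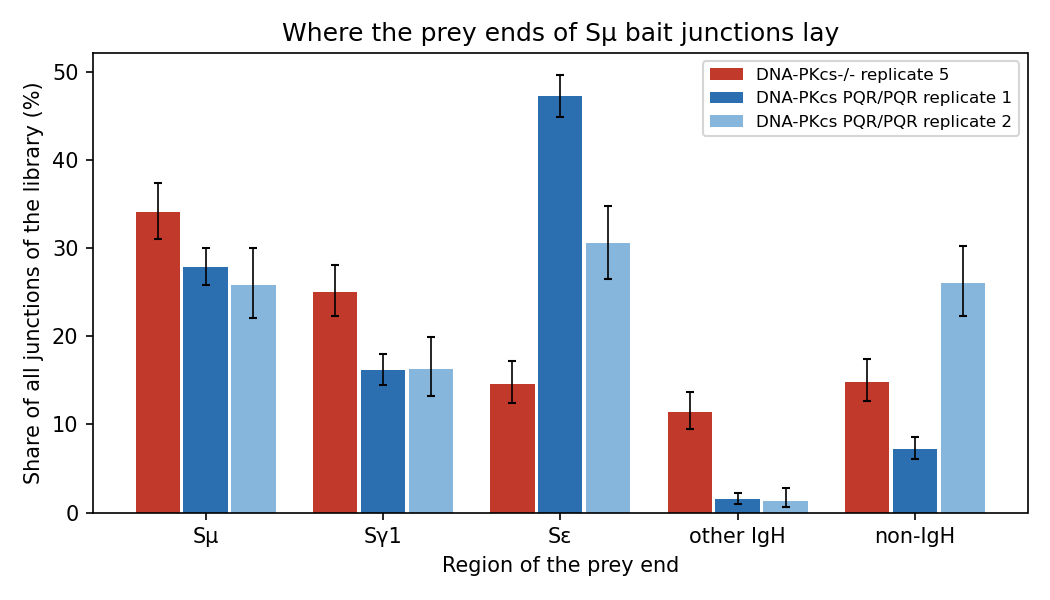
Share of each library's junctions by region of the prey end, in percent of all its junctions, with Wilson 95% intervals as error bars. DNA-PKcs-/- replicate 5 shows the lowest Sε bar and an other IgH bar of 11.4%, against 1.49% and 1.27% in the PQR/PQR libraries.

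Junctions in Sμ and Sγ1 were less often direct in DNA-PKcs-/- replicate 5, and mean MH was longer in all 3 S regions, in Sμ against PQR/PQR replicate 2 alone. Direct joins made up 9.06% of its Sμ junctions (26 of 287, 95% CI 6.26 to 12.9), against 27.1% (127 of 468, 23.3 to 31.3) in PQR/PQR replicate 1 and 24.6% (30 of 122, 17.8 to 32.9) in replicate 2. In Sγ1 they made up 13.3% (28 of 211, 9.34 to 18.5), against 23.5% (64 of 272, 18.9 to 28.9) and 28.6% (22 of 77, 19.7 to 39.5). The adjusted Fisher's exact p was 3.21e-09 and 2.61e-04 for Sμ, and 0.0125 and 0.0118 for Sγ1. In Sε the direct shares were 24.4%, 25.2% and 25%, and no difference was detectable at this depth. The PQR/PQR libraries lay within 5.04 percentage points of each other in the direct share of every S region.

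Mean MH was taken over all junctions without insertion, with direct joins entered as having none. A lower direct share by itself therefore raises it, and the length of MH among MH junctions alone was not tested. Mean MH length of Sγ1 junctions without insertion was 2.51 ± 0.135 bp (SEM over 192 junctions) in DNA-PKcs-/- replicate 5, against 1.75 ± 0.115 bp (236 junctions) and 1.38 ± 0.179 bp (69 junctions) in PQR/PQR replicates 1 and 2. The adjusted permutation p was 1.14e-04 and 6.33e-05. In Sε it was 1.93 ± 0.175 bp, against 1.44 ± 0.0567 and 1.47 ± 0.123 bp, with an adjusted permutation p of 0.00399 and 0.0484. In Sμ it was 2.46 ± 0.110 bp, against 1.80 ± 0.174 bp in PQR/PQR replicate 2, with an adjusted permutation p of 0.00240. MH of 4 bp or longer was called in Sγ1 alone, at 23.7% (95% CI 18.5 to 29.9) against 9.56% (6.61 to 13.6) and 10.4% (5.36 to 19.2), with an adjusted Fisher's exact p of 1.33e-04 and 0.0289. In Sε the shares were 16.3%, 6.80% and 9.72%, and in Sμ 17.4%, 8.55% and 11.5%. In both regions the difference from replicate 1 passed the threshold and that from replicate 2 did not (adjusted Fisher's exact p = 0.225). Insertions were not called in any region, with 18.8% in Sμ of DNA-PKcs-/- against 13.0% and 10.7%, and 5.69% in Sε against 14.2% and 11.1%. The Sε difference passed against replicate 1 (adjusted Fisher's exact p = 0.0151) and not against replicate 2 (0.223), and the difference was -8.54 points without replicate 2. The Sγ1 call for MH of 4 bp or longer was lost, at differences of 12.5 and 15.1 points beside 13.7, when the libraries were thinned to 472 junctions or short preys were removed, and the calls for direct joins in Sγ1 (-12.8 points in both) and for mean MH in Sε (0.400 beside 0.477 bp) were lost with deletional junctions alone, all with fewer junctions. Counting MH from 2 bp gave a call in all 3 regions, with differences of 25.9, 18.1 and 21.1 points in Sγ1, Sε and Sμ, and counting from 6 bp gave none.

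**Figure D2:**
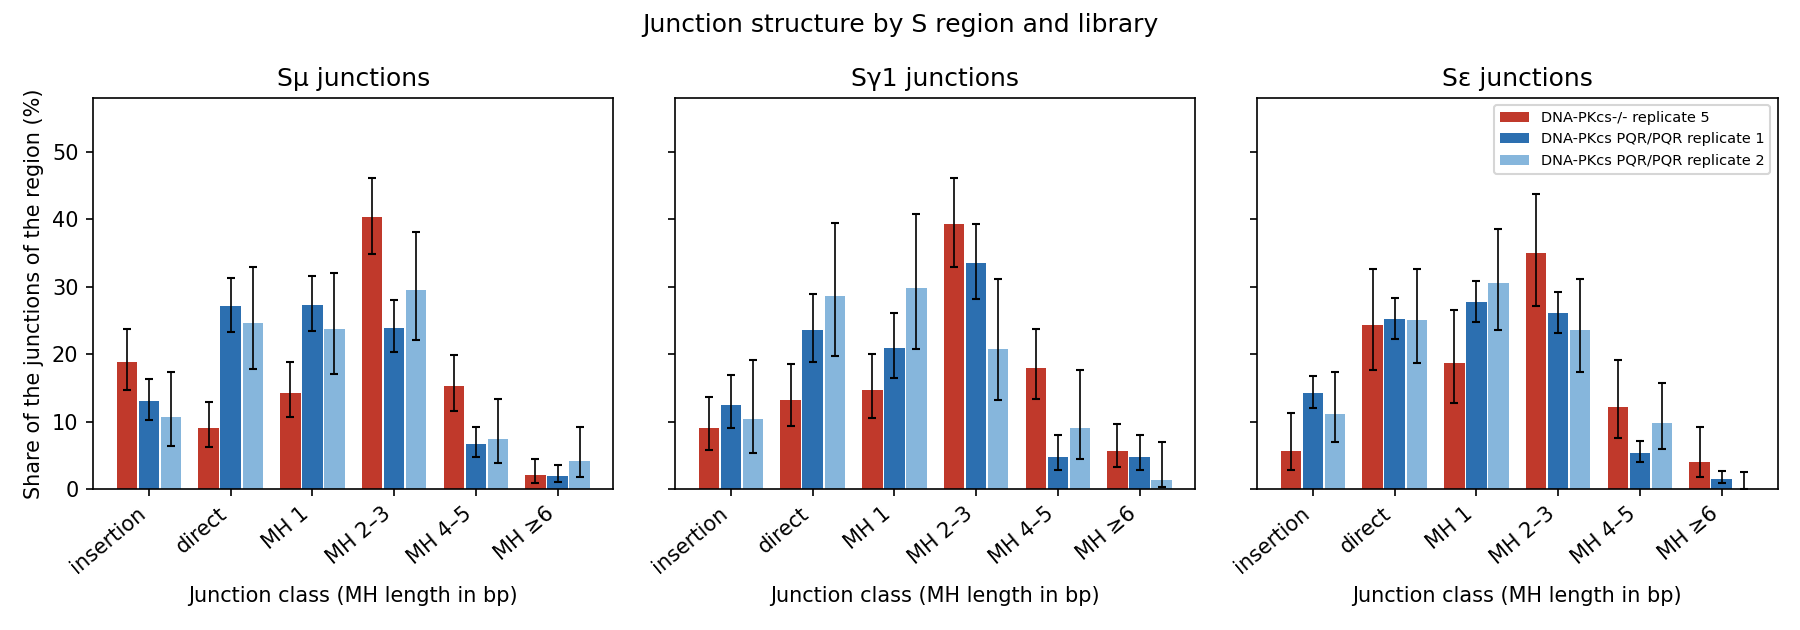
Share of junctions in each class (insertion, direct, or MH by length in bp) for Sμ, Sγ1 and Sε, in percent of the region's junctions, with Wilson 95% intervals as error bars. The direct bars of DNA-PKcs-/- replicate 5 stand at 9.06% in Sμ and 13.3% in Sγ1, below both PQR/PQR libraries, while the Sε bars are level.

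Inverted junctions were not called in any region. In Sμ their share was 39.7% (114 of 287, 95% CI 34.2 to 45.5) in DNA-PKcs-/- replicate 5, 18.6% (87 of 468, 15.3 to 22.4) in PQR/PQR replicate 1 and 36.9% (45 of 122, 28.8 to 45.7) in PQR/PQR replicate 2. The difference from replicate 1 had an adjusted Fisher's exact p of 3.16e-09, that from replicate 2 of 0.789, and the PQR/PQR libraries differed from each other with 1.98e-04. The outcome therefore depended on which PQR/PQR library was used. In Sγ1 the inverted shares were 15.2%, 9.56% and 16.9%, and in Sε 4.88%, 4.66% and 7.64%.

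Prey ends of DNA-PKcs-/- replicate 5 lay further from the bait, at lower mm9 coordinates of chromosome 12, in all 3 S regions. In Sγ1 the mean position was 114570270 ± 350 (SEM), against 114571918 ± 256 and 114572949 ± 523 in PQR/PQR replicates 1 and 2. This is -2164 bp from the PQR/PQR mean, with an adjusted permutation p of 4.89e-04 and 2.85e-04. In Sε the difference was -597 bp, with an adjusted permutation p of 6.33e-05 and 9.50e-05, and in Sμ it was -666 bp, with 6.33e-05 and 0.00919. The adjusted p of 6.33e-05 comes from 1e-05, the smallest that the permutations can give. The SD of positions, which was not tested, was 5077 bp in Sγ1 of DNA-PKcs-/- against 4217 and 4590 bp, 1460 bp in Sε against 910 and 799.9 bp, and 2250 bp in Sμ against 1257 and 1506 bp. The interquartile range, also not tested, was 4096 bp against 8817 and 9016 bp in Sγ1, 1513 bp against 1150 and 1041 bp in Sε, and 3643 bp against 1376 and 1901 bp in Sμ. The lower quartile in Sμ was 114665418 in DNA-PKcs-/-, against 114667652 and 114667209. The Sε and Sμ shifts were smaller and no longer called within the central 95% of all positions, at -247 and -363 bp, and the Sμ medians differed by 42.8 bp in the other direction, while deletional junctions alone gave -1181 bp in Sμ (adjusted permutation p = 0.00104). With the authors' DNA-PKcs-/- pool the Sγ1 mean turned to 257 bp above the PQR/PQR mean, and the Sε shift was -287 bp. All 3 libraries had few Sγ1 junctions from 114572107 to 114575342, which limits their Sγ1 means, ranges and leading bins. The bait break itself was not called, with -3.96 bp between DNA-PKcs-/- replicate 5 and the PQR/PQR mean, and it passed at -5.49 bp without PQR/PQR replicate 1.

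The share of junctions outside the central 95% of positions of all 3 libraries was added after the data had been seen. These limits come from the same positions, so the share outside was fixed over the 3 libraries together. The PQR/PQR libraries supplied most positions and together could not show a high share, so these values describe the libraries and are weak as a test. In Sγ1 it was 12.3% in DNA-PKcs-/- replicate 5 (26 of 211, 95% CI 8.55 to 17.4), with 14 junctions below and 12 above the limits. In PQR/PQR replicate 1 it was 0 of 272, which allows a share of up to 1.10%, and in replicate 2 it was 2.60% (2 of 77). In Sμ the shares were 10.1%, 2.35% and 3.28%. The adjusted Fisher's exact p was 8.86e-10 and 0.0234 for Sγ1, and 2.03e-05 and 0.0453 for Sμ. In Sε they were 12.2%, 4.03% and 4.86% and were not called, with an adjusted Fisher's exact p of 0.00153 against replicate 1 and 0.0642 against replicate 2. The difference was 8.16 points without replicate 2. The Sγ1 difference of 11.0 points was not called with thinned libraries and was 0.845 points with the authors' DNA-PKcs-/- pool. The Sμ call was lost with deletional junctions alone, which are fewer, at a difference of 7.80 points beside 7.29.

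The bins of 500 bp with most junctions were shared in Sμ and Sε. In Sμ all 3 libraries had their leading bins at 114668001 to 114669500, and in Sε at 114513501 to 114515000. The top Sε bin of DNA-PKcs-/- replicate 5, from 114514001 to 114514500, held 21.1% of its Sε junctions (26 of 123), and the same bin held 23.3% (185 of 794) in PQR/PQR replicate 1 and 24.3% (35 of 144) in replicate 2. In Sγ1 the leading bins of DNA-PKcs-/- replicate 5 were the adjacent ones from 114567001 to 114568500, with 9.00%, 10.9% and 12.3% of 211 junctions. PQR/PQR replicate 1 had its leading bins from 114567501 to 114568500 and from 114571001 to 114571500, the last with 10.3%. PQR/PQR replicate 2 led with the bin from 114571001, which held 14.3% (11 of 77), followed by that from 114569001 with 8 junctions. The bins from 114568001, 114568501, 114577001, 114577501, 114578001 and 114579001 held 6 junctions each.

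**Figure D3:**
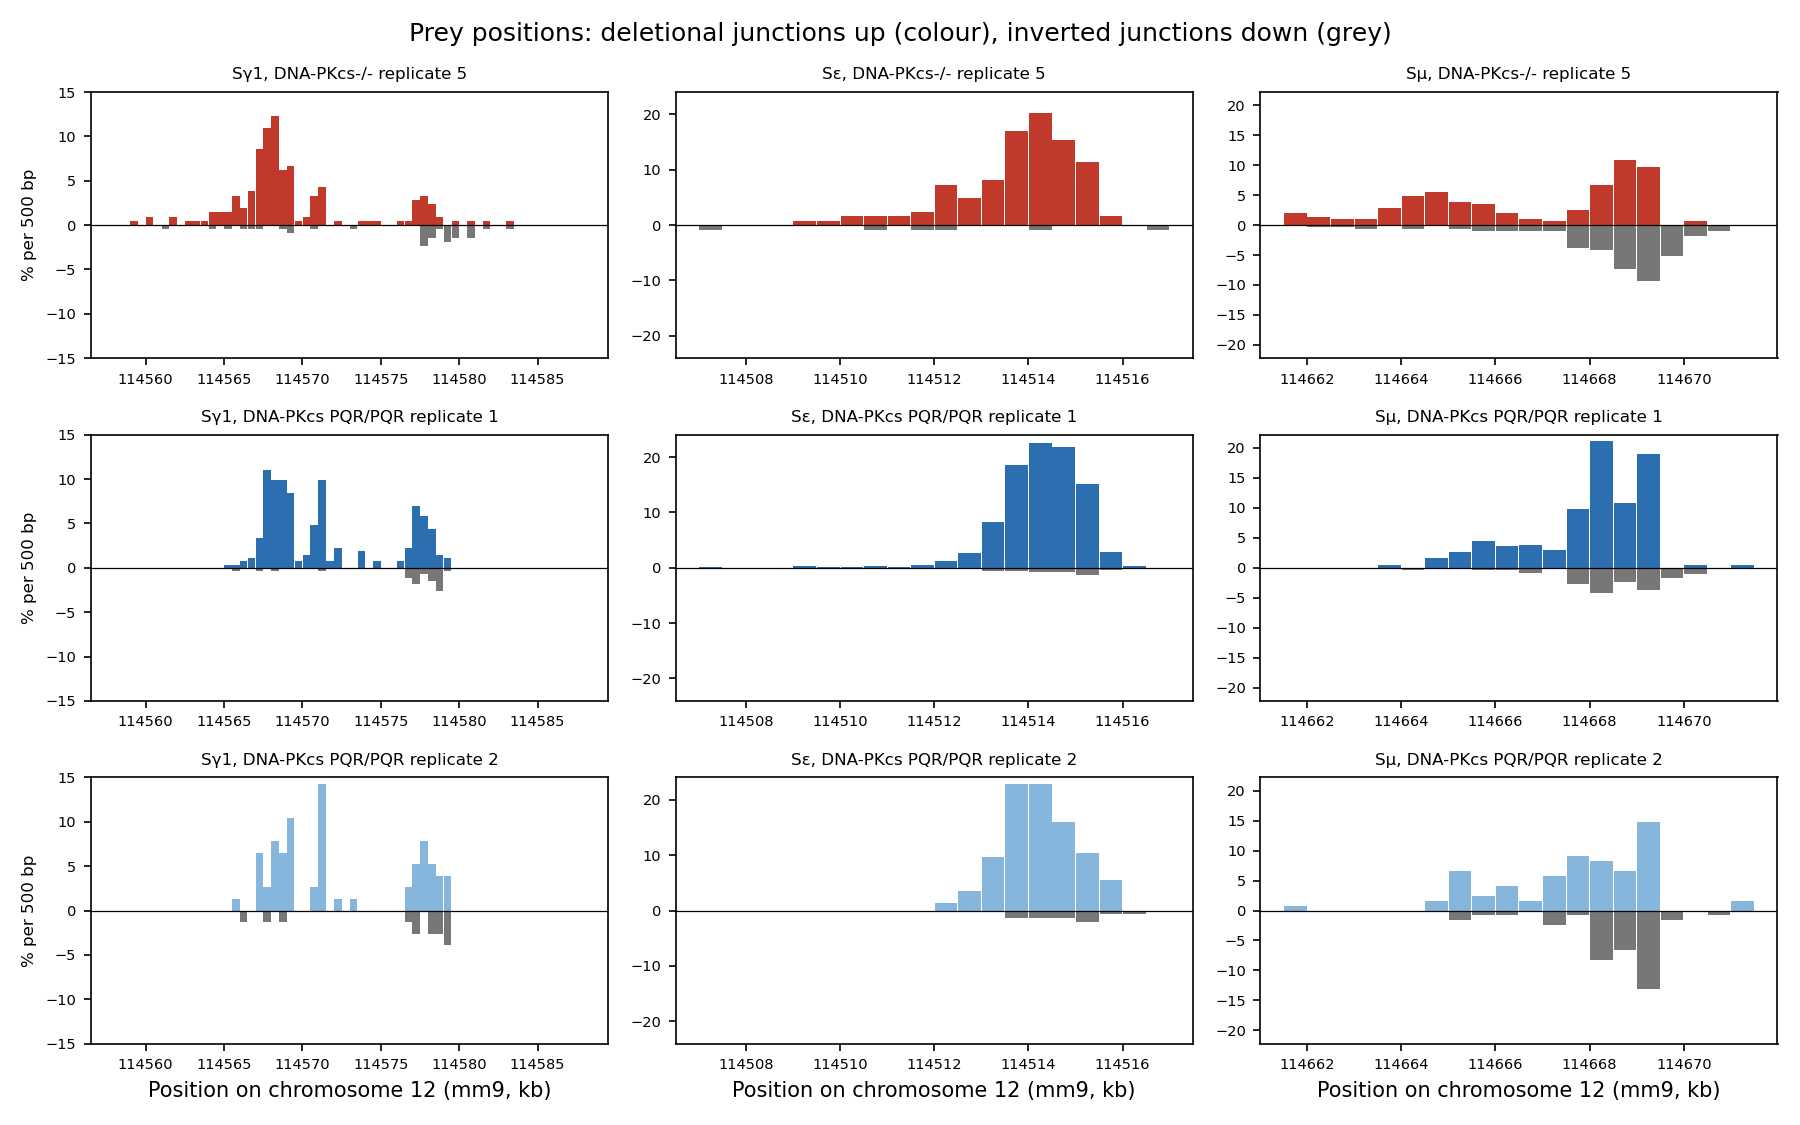
Prey positions in Sγ1, Sε and Sμ (mm9 chromosome 12, kb) as percent of the region's junctions per 500 bp, with deletional junctions upward and inverted junctions downward, in a row per library. DNA-PKcs-/- replicate 5 extends further to both sides in Sγ1 and has larger shares at the lower coordinates of Sμ and Sε.

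Junctions elsewhere in IgH, outside the authors' windows for the S regions, made up 11.4% of all junctions in DNA-PKcs-/- replicate 5 (96 of 842, 95% CI 9.43 to 13.7), against 1.49% in PQR/PQR replicate 1 (25 of 1681, 1.01 to 2.19) and 1.27% in replicate 2 (6 of 472, 0.584 to 2.75). This result was added after the data had been seen. The adjusted Fisher's exact p was 3.42e-25 within the sequencing run and 2.23e-12 against replicate 2. Of the 96 junctions, 22 lay between Sμ and Sγ1, where Ighd and Ighg3 lie, 43 between Sγ1 and Sε, where Ighg2b and Ighg2c lie, and 26 beyond Sε towards Igha. A further 5 lay upstream of Sμ. Ighm, Ighg1 and Ighe, the genes of the 3 S regions, were not placed in an interval. Each interval begins at the edge of an S region's window, so these counts do not part joins near the named genes from spread past a window. Only 3 of the 96 were direct (3.12%, 1.07 to 8.79), against 11 of 25 and 3 of 6 in the PQR/PQR libraries, with an adjusted Fisher's exact p of 3.27e-06 and 0.00466. The difference in the share of other IgH junctions, 10.0 points between these libraries, was 2.32 points with the authors' DNA-PKcs-/- pool.

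Non-IgH junctions made up 14.8% of DNA-PKcs-/- replicate 5 (125 of 842, 95% CI 12.6 to 17.4), 7.26% of PQR/PQR replicate 1 (122 of 1681, 6.11 to 8.60) and 26.1% of PQR/PQR replicate 2 (123 of 472, 22.3 to 30.2). The value of DNA-PKcs-/- lay between those of the PQR/PQR libraries, which differed from each other with an adjusted Fisher's exact p of 3.20e-24, so no direction was called. The authors' DNA-PKcs-/- pool had 5.43%, below both, and the difference from the PQR/PQR mean moved from -1.81 to -11.2 points with it. Chromosome 12, which carries IgH, held most listed non-IgH junctions in DNA-PKcs-/- replicate 5 (16 of 106), followed by chromosome 2 with 8 and chromosomes 9 and 11 with 7 each. Chromosome 12 also led in PQR/PQR replicate 1 (12 of 115), followed by chromosomes 3, 4, 8 and 18 with 9 each. In PQR/PQR replicate 2 chromosome 10 held 10 of 99, chromosome 1 held 9, and chromosomes 2, 11 and 12 held 8 each.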

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

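All tests in this part were chosen after the results had been seen. The authors' pools hold junctions outside the libraries compared here: 2014 in the PQR/PQR pool and 11820 in the DNA-PKcs-/- pool. In the former, 23.5% of Sγ1 junctions were direct and 11.8% had MH of 4 bp or longer. In the latter these shares were 12.4% and 24.4%. The direct share in Sμ was 23.2% in the former and 8.52% in the latter. In Sε it went the other way, at 9.52% (2 of 21) and 18.4% (98 of 533). Sε and Sγ1 went the other way from the libraries: Sε held 1.04% of the 2014 PQR/PQR junctions and 4.51% of the 11820 DNA-PKcs-/- junctions, and Sγ1 held 87.9% and 60.2%. Sμ held 9.83% and 27.4%, higher in DNA-PKcs-/- as in the libraries. The deposited sheets of bait mismatches, which no comparison used, list 59 mismatches in 31273 bait bases of IgH junctions in DNA-PKcs-/- replicate 5 and 130 in 67375 in PQR/PQR replicate 1. For all junctions of PQR/PQR replicate 2 they list 78 in 17378, of which 34 were G-to-T. For Sε junctions of the DNA-PKcs-/- pool they list 2558 in 41258, in 80 reads. These sheets cover different sets of junctions, so their rates are not compared.

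Other IgH junctions were more frequent in DNA-PKcs-/- replicate 5 than in both PQR/PQR libraries. A sequencing run difference is argued against by the comparison within a run, with a Fisher's exact p of 2.28e-26. Spurious alignment of short preys is argued against by the share of preys under 50 bp, 12.5% (95% CI 7.30 to 20.6), since it was 41.5% (32.6 to 51.0) among the same library's non-IgH junctions. Among IgH junctions outside Sγ1, other IgH held 8.97% (8.14 to 9.88) in the rest of the DNA-PKcs-/- pool and 3.95% (2.09 to 7.33) in the rest of the PQR/PQR pool (Fisher's exact p = 0.00743). On this measure DNA-PKcs-/- replicate 5 held 19.0% (15.8 to 22.6), a larger gap to the rest of its own genotype than that between the rests, so genotype and a difference between libraries cannot be told apart, nor can the run for the gaps that involve the rests, since 0 of 529 listed Sε lines of the DNA-PKcs-/- rest and 20 of 20 of the PQR/PQR rest lie in the run of replicate 5.

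The non-IgH share of PQR/PQR replicate 2 was the highest of the libraries, although the numbers of non-IgH junctions were 125, 122 and 123. With preys under 50 bp removed and Sμ left out, its share was 20.4% (95% CI 15.8 to 26.0), against 14.3% (11.3 to 17.9) in DNA-PKcs-/- and 7.20% (5.79 to 8.94) in PQR/PQR replicate 1. The larger Fisher's exact p was 0.0491, unadjusted, the intervals overlap, and with Sμ kept the share was 14.7% against 9.45% in DNA-PKcs-/- (adjusted Fisher's exact p = 0.0572), so short preys stay open. A fixed number of background junctions per library stays open: the rest of the PQR/PQR pool held 16 and that of the DNA-PKcs-/- pool 562, but how many libraries they hold and whether these were made alike is not known here. The run cannot be told apart from the library, since 0 other libraries used here share its run, and of the PQR/PQR rest only 10 of 45 listed lines do, 8 of them non-IgH, with no total for that run.

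Sγ1 junctions of the rest of the PQR/PQR pool, and in part those of the rest of the DNA-PKcs-/- pool, lay where the 3 libraries had few. The lower and upper quartiles of the former were 114572107 and 114575342, and this span held 35.7% (95% CI 34.6 to 36.8) of Sγ1 junctions in the rest of the DNA-PKcs-/- pool, 4.78% in PQR/PQR replicate 1, 2.60% in replicate 2 and 2.37% in DNA-PKcs-/- replicate 5. For the PQR/PQR rest, a difference limited to Sγ1 is argued against by Sμ. There 16.7% (95% CI 12.1 to 22.5) of its junctions lay between the quartiles of the PQR/PQR libraries' positions. The share was 37.3% (31.9 to 43.0) in DNA-PKcs-/- replicate 5 and 43.0% (41.3 to 44.7) in the rest of its pool, which did not set this span. The PQR/PQR libraries, which set it, had 51.7% in replicate 1 and 42.6% in replicate 2. The 43.0% of the DNA-PKcs-/- rest lies among the values of the libraries. For that rest a difference limited to Sγ1 therefore stays open. An IgH allele that differs from the reference and a different preparation or filtering of the libraries cannot be told apart by the 4.78%, which both would give. Of 45 listed lines of the PQR/PQR rest, 77.8% came from the run of replicate 1 and 22.2% from that of replicate 2. These lines point to no other run. The run stays open only because the Sγ1 lines of the PQR/PQR rest are not analysed here. No biological explanation was tested, as the labels give these junctions no group beyond the genotype.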

How the results depend on the processing

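Of 245 values under alternatives, 192 kept the direction and the side of the threshold, or stayed within the spread. Values are DNA-PKcs-/- minus PQR/PQR, in percentage points unless in bp; unless construction shows it, the cause was not tested. The lower direct share in Sμ kept its call in every alternative with a test, against PQR/PQR replicate 2 alone with preys of 50 bp or longer, and its direction with the DNA-PKcs-/- pool, from -23.4 to -14.5. The longer mean MH in Sγ1 kept its call in the 7 alternatives run, from 0.756 to 1.13 bp. In Sμ mean MH compares PQR/PQR replicate 2 alone, so leaving out replicate 1 only repeats that comparison; its values were 0.665 to 1.03 bp, and the DNA-PKcs-/- pool among them has no test. Collapsing repeated junctions changed no call but could hardly do so. The lists collapsed held 3 repeats in Sε, 2 in Sγ1 and 1 outside IgH, all in PQR/PQR replicate 1. The sheet of large insertions likewise added at most 2 lines to a region of a library. The 28 and 12 values of these settings are among the 192. Leaving out a PQR/PQR library gave ranges of -11.2 to 7.59 (non-IgH), -1.72 to 5.61, -2.76 to 0.218 and 2.84 to 21.1 (inverted Sγ1, Sε, Sμ), 6.54 to 9.46 and 5.95 to 8.87 (MH of 4 bp or longer in Sε, Sμ), -8.54 to -5.42 and 5.78 to 8.16 (insertions in Sε, Sμ), 7.33 to 8.16 (Sε tails) and -5.49 to -2.43 bp (bait). None of these was called with both libraries. Without replicate 2, calls came for inverted Sμ, MH of 4 bp or longer and insertions in Sε and Sμ, and Sε tails, and non-IgH was called higher in DNA-PKcs-/-; without replicate 1, they came for Sε tails and the bait position, and non-IgH was called lower. The calls for Sε tails without replicate 1 (adjusted Fisher's exact p = 0.0428) and for insertions in Sμ without replicate 2 (0.0491) come from fewer tests in the adjustment, since the comparison itself is one already made. The DNA-PKcs-/- pool, without a test, gave 43.6, -41.2 and -2.39 for Sγ1, Sε and Sμ shares, -11.2 for non-IgH, -5.23 for inverted Sγ1, -5.58 for direct Sε, 14.4 for MH of 4 bp or longer in Sγ1, 2.66 and -1.24 for insertions in Sγ1 and Sε, 2.32 for other IgH and -38.5 for its direct share, 0.845, 5.16 and 5.41 for Sγ1, Sε and Sμ tails, 0.606 bp for mean MH in Sε, and 257, -287 and -563 bp for Sγ1, Sε and Sμ positions. The PQR/PQR pool gave -20.8 for the Sγ1 share, 8.58 for non-IgH, 10.4 and 20.9 for inverted Sγ1 and Sμ, 9.07 and 9.17 for MH of 4 bp or longer in Sε and Sμ, -8.28 for insertions in Sε and 7.92 for Sε tails; the calls among these come with more junctions and 1 comparison in place of 2. MH of 2 bp or longer was called in Sε (18.1) and Sμ (21.1), and MH of 6 bp or longer was not in Sγ1 (2.65) and turned in Sμ (-0.920). Deletional junctions alone, fewer in number, lost the calls for direct Sγ1 (-12.8), Sμ tails (7.80) and mean MH in Sε (0.400 bp). Medians lost the Sε position (-259 bp) and turned Sμ (42.8 bp), and positions inside the percentiles lost Sε (-247 bp) and Sμ (-363 bp), which by construction removes the tails. Preys of 50 bp or longer lost MH of 4 bp or longer in Sγ1 (15.1) and turned inverted Sγ1 (-0.192). Thinning to 472 junctions lost MH of 4 bp or longer in Sγ1 (12.5 beside 13.7) and Sγ1 tails (8.87 beside 11.0), and the bait position passed (-5.73 bp). The thinning was a random draw that was not repeated, so these changes may depend on the draw as well as on fewer junctions. Bait positions from Sγ1 and Sε alone, chosen after seeing the data, changed nothing. Bait positions and Sγ1 mean MH were not run with the pools, and Sμ mean MH was not run with the PQR/PQR pool or without replicate 2. With repeats collapsed, the Sμ counts of PQR/PQR replicate 1 stayed as they were. Positions in that setting came from the lists, so Sμ positions and tails compare PQR/PQR replicate 2 alone. Lines not used here dropped out too, and the Sε tail share of DNA-PKcs-/- replicate 5 was 11.5% beside 12.2%. With preys of 50 bp or longer the region, non-IgH and other IgH shares and all Sμ results compare PQR/PQR replicate 2 alone. The shares of MH of 4 bp or longer that were not called rest on 123 to 794 junctions per library in Sε and 122 to 468 in Sμ. No paired analysis was possible because the groups share no replicate number.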

Other observations

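The tests in this part were chosen after the results had been seen. Lower-case letters, read here as repeat-masked, were counted in the 20 reference bases centred on the prey junction. They were at least as many as upper-case letters for 57.5% of listed non-IgH junctions in DNA-PKcs-/- replicate 5. This share was 52.2% in PQR/PQR replicate 1 and 51.5% in PQR/PQR replicate 2. The share was 0 in each listed S region of each library. S region preys lie in fixed windows, so their masking follows from the reference there. A share for the whole genome was not computed, so these values show no preference of junctions for or against repeats. Among other IgH junctions it was 3.12% (3 of 96) in DNA-PKcs-/- replicate 5, 8% (2 of 25) in PQR/PQR replicate 1 and 0 of 6 in replicate 2. S region junctions were dispersed. The most frequent single prey position of the lists was 114513709 on chromosome 12 in Sε of PQR/PQR replicate 1, in GTCTAGCCCAGCCCCTCTCA, with 3 of 789 junctions at 3 different bait positions.

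With mean positions of DNA-PKcs-/- replicate 5 further from the bait, the hypothesis was tested that its junctions were less often near AGCT, a preferred target motif of the deaminase AID. Within 20 reference bases, AGCT was present at 37.6% of Sμ junctions in DNA-PKcs-/- replicate 5 against 50.8% in PQR/PQR replicate 2, and at 23.2% of Sγ1 junctions against 31.9% and 32.5%. The share was lower in DNA-PKcs-/- in 7 of 7 comparisons over Sμ, Sγ1, Sε and other IgH, which share the same DNA-PKcs-/- junctions. None passed the threshold after adjustment, and the smallest adjusted Fisher's exact p was 0.111, so the hypothesis stays undecided at this depth.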
